A study of Caenorhabditis elegans with 5 samples.

How the data were processed

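Small RNAs of adult worms were sequenced in 5 libraries, 1 per group: RNA from a CSR-1 immunoprecipitate of wild-type N2 animals, N2 input, DA1316, and the mutants ego-1(om97) and csr-1(tm892). Per the labels' protocols, animals were grown at 20 °C for about 60 h, and the mutants and DA1316 were counter-selected on ivermectin. Small RNA was excised from a gel between standards of 18 and 26 nt. For the IP and its input the labels also state a treatment with Tobacco Acid Pyrophosphatase, which opens 5′ triphosphates for ligation, then linker ligation, PCR and Solexa sequencing. The text of the labels breaks off after the gel step for the other 3 libraries, so whether they had this treatment is not given in the sources used here. The IP pair and the other 3 libraries were therefore compared within their own set, except for the yardstick of N2 input against DA1316. A ratio of 21U-RNAs in ego-1 to N2 input was computed after the data were seen and is not used.

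The deposited files list each sequence of 17 to 30 nt at each of its places in the genome, without headers. The authors deposited read counts, 1 per sequence and library, without scaling to depth. A further deposited column holds another kind of value, the number of places a sequence matches. The expected counts in the deposited files are the reads of a sequence divided by that number, and they sum to the reads of the library. These meanings were read from the values, since the labels do not state them. The aligner and the genome build are not given in the sources used here.

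The annotation at hand was Ensembl release 115 on WBcel235, so the fit of the files to that build was measured first. Reads that span exon junctions gave 31965 spans of introns of at least 150 nt, of which 29606 matched 1 annotated intron of equal length and 2149 matched none. The offset between the files and the annotation changed along each chromosome, by a median of at most 121.0 nt at the farthest windows (chromosome III). No coordinate was converted. An offset range was set for each window of 500000 bp, without the most extreme junction reads and widened by 3 nt. A read was assigned to an exon only where its midpoint lay inside the exon under every offset in that range. Reads that span a junction were instead assigned where their whole span lay inside a single gene, introns included. Reads on chromosome V from position 19500001 had no stable offset and were not placed. Positions printed in the report are the files' own, in the unnamed build. Symbols came from the RefSeq gene table where a gene had the same position and biotype there (88.0% of 19985 protein-coding genes). Otherwise the Ensembl name was kept. Pseudogenes (2128) were counted separately.

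Each read was put in 1 class: structural RNA (with the rRNA gene unit on chromosome I and 3000 nt before it), miRNA, 21U-RNA, antisense to protein-coding exons, antisense to pseudogenes, sense, other or not placed. A 21U-RNA was a read of 17 to 21 nt that starts with U at the 5′ end of an annotated piRNA. Shares have exact Clopper-Pearson intervals. The level of a gene was its antisense reads, weighted by 1 over the number of matches, in RPM of non-structural reads. Log2 ratios used a pseudocount of 1 RPM, and folds beside an interval are plain ratios. A gene was measured when it reached 10 RPM in the higher library, and was called at a fold of 2. Intervals of ratios are exact conditional binomial intervals at 95%. They and the floor of 3 reads cover counting error only. A gene with 0 reads in 1 library was given a bound against a floor of 3 reads in that library. With 1 library per group no p-value is printed. Depth is given in the report; libraries had between 1887 (ego-1) and 5816 genes (CSR-1 IP) at 10 RPM.

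The median of each gene list is given with an order-statistic interval and with its percentile among 10000 random lists of equal size and level, which describes these libraries only. The 16 lists, the comparisons, the size rule and the rule for named genes were fixed before the data were examined. The lists were Argonautes (22 names, 20 matched), RNA-dependent RNA polymerases and biogenesis (28, 24 matched), P granule (17), oocyte and maternal mRNA regulators (34), sperm (54), kinetochore and chromosome segregation (49), meiosis and synapsis (41, 40 matched), cell cycle and replication (41), chromatin (38), core histones with the linker histone his-24 (72), ribosomal proteins (90, 83 matched), muscle (26), intestine (34, 33 matched), neuron (37), cuticle collagen and hypodermis (49) and ERGO-1 targets (21, 11 matched). Lists with fewer than 3 measured genes have no median. Named genes were csr-1 and ego-1; the 6 largest and 6 smallest log2 ratios among genes with a mean of at least 25 RPM and at least 50% of reads matching 1 place; the 2 members of each list with the highest level in the control library; and the 4 miRNAs with the most reads in N2 input. Other genes named with their list were named after their values were seen. The names and read numbers of the sperm genes higher in ego-1 are not reported here.

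Overlaps of lists are given beside the number for independent lists. Because csr-1 and ego-1 share DA1316, their overlap was also computed for 100 simulated sets of unchanged libraries against the same control, with counting error alone and with a spread of 0.753 (SD of log2) as between N2 input and DA1316, and with the DA1316 reads split in 2. The added spread had no general shift up or down.

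Alternatives tried were miRNA reads or all genome-matched reads as the normaliser, a minimum of 25 RPM or none beyond 1 read, a fold of 4, a pseudocount of 0.1 RPM, 21- to 23-nt reads that start with G, reads with 1 match, distinct sequences counted once, and whole genes with introns. Reads of at least 21 nt and centring on the median of measured genes were added after seeing the data. The shortened 21U-RNAs, the wider rRNA unit, the offset rule with the end of chromosome V, the position of reads along genes, the miRNA families, the matched X-linked comparison and the list medians with members at their bound were also chosen after seeing the data.

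The placing of reads was tested on 49389 simulated reads, of which 99.2% were placed and 100.0% of those in the right gene. Each simulated read was shifted by the midpoint of its window's own offset range. Placing in the right gene thus followed from the rule, and the fit of the offsets to the files was not tested by it. Calls were tested on simulated counts with 50 genes changed 4-, 8-, 0.25- and 0.12-fold each. In the simulated IP (1778 genes), csr-1 (3286 genes) and ego-1 comparison (3286 genes) 100.0% were called at each fold size, and 0.13%, 0.03% and 0.1% of unchanged genes. These counts held counting error only and came from genes whose control level lay above the 10 RPM minimum. The share of unchanged genes called is therefore not an error rate for real libraries. N2 input and DA1316 carry neither mutation, yet 123 genes were called higher and 1732 lower of 5328. Of random lists, 6.0% lay outside the percentiles that hold 95% of lists. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.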

Results

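Small RNAs of adult Caenorhabditis elegans were sequenced in 5 libraries, 1 per group. One pair held the small RNAs that co-purified with CSR-1, an Argonaute protein that binds germline small RNAs, and the small RNAs of the wild-type N2 animals that served as input. The other libraries came from csr-1(tm892) mutants, from ego-1(om97) mutants, which carry a mutation in an RNA-dependent RNA polymerase gene, and from DA1316, which the labels give as the wild-type control for both mutants. The mutants and DA1316 were counter-selected on ivermectin and N2 was not. The libraries held 1347558 reads (CSR-1 IP), 3124393 reads (N2 input), 3309185 reads (csr-1), 2773473 reads (ego-1) and 3328398 reads (DA1316). Without replicates there is no spread between samples, so a difference was named only by its size. A gene was called higher or lower when its antisense level differed at least 2-fold and reached 10 RPM (reads scaled to the library's non-structural reads) in the higher library. Intervals in parentheses after a share or a ratio are 95% intervals that cover counting error only. Since reads amplified by PCR without molecular identifiers are not independent molecules, these intervals are narrower than the true error. Intervals after a median are 95% order-statistic intervals across genes, which are not independent of each other. No comparison has a replicate check, and each one compares libraries, not conditions.

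The composition of the libraries differed widely. Reads antisense to protein-coding exons made up 59.6% of the CSR-1 IP (59.5 to 59.7%, exact Clopper-Pearson interval) against 18.5% of its input (18.5 to 18.6%). The share was 23.2% in csr-1 (23.1 to 23.2%), 10.1% in ego-1 (10.1 to 10.2%) and 23.2% in DA1316 (23.2 to 23.3%). These shares depend on the amount of structural RNA. Of non-structural reads alone they were 65.15% in the IP, 18.8% in N2 input, 36.1% in csr-1, 18.3% in ego-1 and 28.7% in DA1316. In all 5 libraries between 73.9% and 77.6% of these antisense reads started with G. Their most common length was 22 nt in the IP (46.1%), N2 input (52.8%), csr-1 (44.7%) and DA1316 (43.4%), whereas 22-nt reads were 28.3% of the antisense reads in ego-1. MicroRNAs, which other Argonautes bind, went from 40.04% of the input to 13.6% of the IP, and 21U-RNAs, the piRNAs of the worm germline, from 21.9% to 4.57%. Fragments of rRNA, tRNA and other structural RNAs took 8.53% of the IP, 1.62% of N2 input, 35.9% of csr-1, 44.6% of ego-1 and 18.98% of DA1316. They were left out of the library sizes, which leaves 1232572 reads in the IP, 3073695 in N2 input, 2120426 in csr-1, 1536409 in ego-1 and 2696496 in DA1316. Short reads of 17 to 20 nt formed 10.1% of all reads in the IP, 5.64% in N2 input, 20.1% in csr-1, 47.1% in ego-1 and 16.5% in DA1316.

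**Figure D1:**
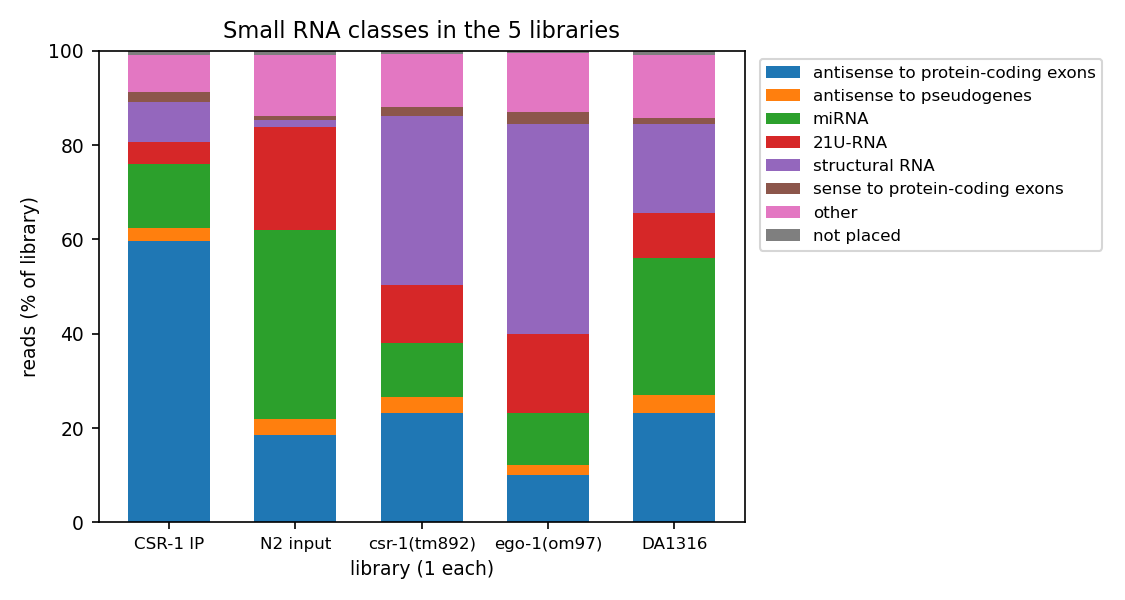
Share of reads in each small RNA class (y axis, % of the library's reads) for the 5 libraries, 1 bar per library and 1 colour per class. Reads antisense to protein-coding exons take 59.6% of the CSR-1 IP and 10.1 to 23.2% of the other libraries, and structural RNA takes 35.9% and 44.6% of the csr-1 and ego-1 libraries. Of non-structural reads alone the antisense share is 36.1% in csr-1, 18.3% in ego-1 and 28.7% in DA1316.

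The CSR-1 IP was compared with its input to ask which genes have antisense small RNAs that co-purify with CSR-1. Germline genes of almost every kind on the fixed lists were higher in the IP. Antisense small RNAs of csr-1 itself were 11.16-fold higher (9.58 to 13.1) and those of ego-1 9.35-fold higher (7.82 to 11.17). In the files' own coordinates their reads spanned chromosome IV 7957263 to 7962104 and chromosome I 7650342 to 7656329. With whole genes in place of exons csr-1 was not measured. Of 6098 protein-coding genes measured, 4777 were higher in the IP and 561 lower, with a median log2 ratio of 2.68. A gene could be measured through its IP level alone, since 5816 genes reached 10 RPM in the IP and 3642 in N2 input. Which genes were measured thus depended in part on the enrichment itself, and so did the counts and medians of the lists below. With no minimum beyond 1 read, 5566 of 12365 genes were higher and the median was 0.857. Of 278 pseudogenes, 27.3% were higher and 37.4% lower, with a median log2 ratio of −0.43.

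Chromosome segregation genes stood highest. All 48 measured kinetochore and chromosome segregation genes were higher in the IP, with a median log2 ratio of 3.46 (3.21 to 3.597) that lay at percentile 99.98 of 10000 random lists matched on level. Among them klp-7, a microtubule-depolymerizing kinesin, was 12.8-fold higher (11.4 to 14.3) and cls-2, a CLASP protein of the kinetochore, 3.62-fold higher (3.26 to 4.03). All 39 measured cell cycle and replication genes were higher, with a median of 3.35 at percentile 98.81. The DNA topoisomerase gene top-2 was 11.64-fold higher (10.2 to 13.4) and the mitotic kinase gene cdk-1 6.23-fold higher (5.22 to 7.46). The 33 measured oocyte and maternal mRNA regulators were all higher, with a median of 3.26 at percentile 98.36. The germline Notch receptor gene glp-1 was 4.59-fold higher (3.65 to 5.79) and fbf-1, a Pumilio-family translational regulator, 8.35-fold higher (6.64 to 10.6). All 39 meiosis genes were higher as well, with a median of 2.99 at percentile 68.04, which placed them near other genes of their level. The HORMA-domain gene htp-1 was 6.76-fold higher (5.70 to 8.04) and hal-2 5.55-fold higher (4.55 to 6.79). Ribosomal protein genes, a housekeeping class, were higher in 71 of 71 cases, with a median of 2.84 at percentile 99.94, and rpl-11.1 was 7.78-fold higher (5.04 to 12.203) and rpl-13A 3.42-fold higher (2.03 to 5.84). Only 22 ribosomal protein genes were measured in N2 input against DA1316, so most of the 71 reached 10 RPM in the IP only.

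Small RNA pathway genes showed the same direction with some exceptions. All 14 measured Argonaute genes were higher, with a median of 3.10 at percentile 84.3. The nuclear Argonaute gene hrde-1 was 7.92-fold higher (7.07 to 8.92) and the PIWI gene prg-1 2.74-fold higher (2.43 to 3.09). Of 24 genes for RNA-dependent RNA polymerases and small RNA biogenesis 22 were higher, with a median of 3.01 at percentile 68.62, and rde-11 (log2 −0.97) and rrf-2 (log2 −0.32) were called neither way. Among 17 P granule genes 16 were higher, with a median of 2.96 at percentile 62.54. The Vasa-related helicase genes glh-1 and glh-4 were 9.88-fold (8.43 to 11.55) and 7.10-fold higher (6.00 to 8.40), although only 33.6% of the glh-4 reads matched 1 place in the genome. Chromatin genes were higher in 34 of 35 cases, with a median of 3.04 at percentile 71.31. The histone methyltransferase gene set-2 was 7.25-fold higher (6.24 to 8.44) and lin-35, the worm retinoblastoma homologue, 5.06-fold higher (4.23 to 6.10). Of 11 measured histone genes 8 were higher and 1 was lower, the linker histone gene his-24 at 2.57 times below input (2.24 to 2.96), and his-35 (log2 −0.68) was called neither way. The histone list had a median of 2.602 at percentile 50.63.

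Lists for other cells were barely measured. Only 3 of 54 sperm genes reached the minimum level, with a median log2 ratio of 1.61 at percentile 18.92. With distinct sequences the same 3 had a median of 0.81, while the 11 sperm genes measured under that choice had −2.08. In the IP spe-39 was 5.57-fold higher (3.97 to 7.92), and spe-41 was 2.51 times lower (1.54 to 4.32). From the muscle list pat-3, a β-integrin gene, was measured at 5.74-fold higher (4.17 to 8.01), from the intestine list the vitellogenin gene vit-6 at 7.48-fold higher (2.84 to 23.02), and no cuticle collagen or hypodermis gene was measured. The synaptic gene snb-1 was 6.82-fold higher (3.97 to 12.22), and unc-10 (log2 −0.29) was not called. Genes listed as targets of ERGO-1, an Argonaute of 26-nt small RNAs, did not follow the germline lists. Of 9 measured, 2 were higher, 3 were lower and 4 were called neither way, with a median of −0.60 at percentile 3.72 that turned to 1.16 with miRNA scaling and to 0.625 with 21- to 23-nt reads that start with G. E01G4.5 was 5.42-fold higher (5.16 to 5.70), while Y37E11B.2 (log2 −0.81) was not called.

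The largest ratios among well-covered genes were Y116A8C.9 (54.3-fold, 44.8 to 66.1), T27F6.6 (39.9-fold, 31.7 to 51.3), arp-11 (38.6-fold, 23.6 to 67.2), zipt-15 (35.4-fold, 26.1 to 50.0), Y56A3A.28 (33.4-fold, 26.0 to 43.2) and clu-1 (32.3-fold, 25.7 to 41.24). Reads of Y116A8C.9 spanned chromosome IV 16939171 to 16946757. At the other end, small RNAs of the ciliary transition zone genes mksr-2 (7.86 times lower, 5.02 to 13.01) and mks-1 (7.91 times, 4.33 to 16.1) were depleted. So were those of gpa-9, a G protein α subunit gene (6.61 times, 4.90 to 9.10), lon-8 (7.07 times, 3.49 to 16.7), oac-59 (6.31 times, 4.10 to 10.2) and the Wnt gene egl-20 (6.22 times, 3.19 to 13.9). Reads of mksr-2 spanned chromosome IV 2304290 to 2306548. Scaling to miRNA reads moved the median by 1.31 and gave 5671 genes higher and 26 lower, which ended the calls of spe-41 and his-24. The call of spe-41 also ended with 21- to 23-nt reads that start with G (log2 −0.99). Counting each distinct sequence once gave 3733 higher and 1974 lower, so that 65.4% of calls were higher in place of 89.5%, and ended the calls of Y116A8C.9, Y56A3A.28, prg-1, hrde-1, glh-4, glp-1, spe-39, cls-2, htp-1, hal-2, cdk-1, rpl-11.1, rpl-13A and E01G4.5. Centring on the median gene, chosen after seeing the data, takes out the general enrichment by construction and gave 784 higher and 1726 lower, with medians of −1.07 for sperm and −0.077 for histone genes.

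Among microRNAs, the 4 most abundant in the input were all lower in the IP. The level of mir-58.1 in the IP was 29.3% of its input level, mir-80 stood at 45.9%, mir-72 at 36.03% and mir-52 at 90.8%. As classes, miRNAs were 2.73 times and 21U-RNAs 4.45 times lower in RPM than in the input. Structural RNA went the other way, from 1.62% of all reads in the input to 8.53% in the IP, and mitochondrial reads rose from 0.286% to 1.88%. No mock immunoprecipitation was analysed here, so background was not measured.

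The csr-1(tm892) library was compared with DA1316 to ask which small RNAs depend on csr-1. The antisense small RNAs of the csr-1 gene stood at 0.848 of the DA1316 level (0.719 to 1.00) and those of the ego-1 gene at 1.48 (1.26 to 1.74), neither passing the size rule. The csr-1 total hides differences along the gene, shown by stretches named after their values were seen. Unscaled reads from 7958963 to 7959062 numbered 0 against 30 in DA1316. From 7961663 to 7961762 they numbered 61 against 20. Antisense reads of either gene do not check the genotype, because they are made from the transcript and the limits of the deletion are not in the labels. Of 5739 genes measured, 1011 were higher and 1776 lower, with a median log2 ratio of −0.26. Among 324 pseudogenes 74 were higher and 133 lower. The split depended on the scaling. With miRNA reads as the normaliser 2673 genes were higher and 718 lower, with the median shifted by 0.98, and 78.8% of calls were higher in place of 36.3%. With all genome-matched reads 641 were higher and 1985 lower, a share of 24.4%, with the median shifted by −0.31. Centred on the median gene, 1324 were higher and 1463 lower, a share of 47.5%.

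Most germline lists that were high in the IP moved little in csr-1 mutants. Of 45 measured chromosome segregation genes, 32 were called neither way, 5 were higher and 8 lower, with a median log2 ratio of −0.22 (percentile 3.86) that turned to 0.80 with miRNA reads as the normaliser. The higher genes included cls-2 (2.30-fold, 2.11 to 2.52) and klp-7 (2.02-fold, 1.83 to 2.23), and the lower ones smc-4 (log2 −2.55) and sas-6 (log2 −1.81), named after their values were seen. The calls of cls-2 and klp-7 ended with all genome-matched reads as the normaliser, with distinct sequences and with 21- to 23-nt reads that start with G, and that of klp-7 also with reads of at least 21 nt. Cell cycle genes had 5 higher, 5 lower and 28 neither (median −0.01, percentile 44.99; 0.98 with miRNA scaling), with top-2 at log2 −0.29 and plk-1 at log2 −0.33. Meiosis genes had 2 higher, 6 lower and 29 neither (median −0.14, percentile 47.4; 0.86 with miRNA scaling), with htp-1 at log2 0.43 and hal-2 at log2 0.72. Oocyte and maternal genes had 4 higher, 6 lower and 22 neither (median −0.28, percentile 29.18; 0.71 with miRNA scaling). The yolk receptor gene rme-2 was 2.96 times lower (2.18 to 4.07), a call that ended with miRNA scaling, while glp-1 (log2 −0.55) was not called. The higher members were puf-3, puf-11, fog-1 and fog-3, all regulators of germline mRNAs or sex, and were named after their values were seen. Beside these lists, the 8 members of the mir-35 family, microRNAs of oocytes and embryos, were 8.31 times lower together in csr-1 mutants than in DA1316 (8.13 to 8.497), while other miRNAs were 1.90 times lower. N2 input had 1.58 times the DA1316 level of this family. The family was chosen after its values were seen.

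Ribosomal protein genes moved further, with 19 of 24 lower, 1 higher and 4 neither. In N2 input against DA1316, 18 of 22 were also lower, with a median of −1.22. The csr-1 median was −1.66 (−2.07 to −1.25), at percentile 52.05 of lists of equal level. With miRNA scaling the same 24 genes had a median of −0.77, while the 13 that were measured under that scaling had 0.60. The genes rpl-11.1 (12.19 times lower, 4.53 to 46.1) and rpl-13A (5.54 times lower, 2.99 to 11.08) were among them, and rpl-42 was the higher member. P granule genes had none higher, 4 lower and 11 neither (median −0.75, percentile 4.18; 0.27 with miRNA scaling), with pgl-1 at log2 −0.49 and glh-4 at log2 −0.75. The lower ones were pgl-3, glh-2, meg-3 and meg-4. Chromatin genes had 3 higher, 7 lower and 24 neither (median −0.38, percentile 8.57; 0.66 with miRNA scaling). The nucleosome remodeller gene isw-1 was 8.54 times lower (5.79 to 13.1), and set-2 (log2 0.46) was not called. The biogenesis list had 3 higher, 5 lower and 14 neither (median −0.31, percentile 6.05; 0.79 with miRNA scaling). From that list rde-11 was 2.97-fold higher (2.72 to 3.25), a call that ended when distinct sequences were counted. Argonaute genes went both ways (3 higher, 4 lower, 7 neither, median −0.81, percentile 7.36; 0.19 with miRNA scaling). The sperm-pathway Argonautes alg-3 and alg-4 and the germline Argonaute wago-4 were higher, and nrde-3, ppw-1, sago-2 and alg-5 lower. Neither prg-1 nor hrde-1 was called, both at log2 −0.91.

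Of the lists for other cells, 4 of 6 measured neuronal genes were lower and 1 was higher, egl-21 (median −2.15, percentile 0.80). With miRNA scaling the same 6 had a median of −1.29, while the 9 measured under that scaling had 0.38. The synaptic active zone gene unc-10 was 27.4 times lower (18.6 to 42.2) and the vesicular acetylcholine transporter gene unc-17 15.0 times lower (7.44 to 35.5). The cuticle gene noah-2 was 30.4 times lower (8.10 to 254). With whole genes in place of exons unc-17 was not measured in either mutant, and noah-2 was not called in csr-1 (log2 −0.51) or in ego-1 (log2 −0.55). The giant muscle kinase gene ttn-1 was 2.86 times lower (1.57 to 6.25), with 36.97% of its reads matching 1 place and no call with miRNA scaling, and pat-3 was not called (log2 −0.05). No intestinal gene was measured. Sperm genes numbered 3 higher (spe-39, fer-1, ssp-16), 2 lower (spe-44, spe-15) and 1 neither, spe-41 (log2 −0.44), with a list median of 0.35 (percentile 92.1). With 21- to 23-nt reads that start with G the same 6 had a median of 0.085 and the 5 still measured −0.65. With reads that match 1 place these were 0.33 and −0.41. The spe-39 call (2.26-fold higher, 1.63 to 3.17) ended with all genome-matched reads as the normaliser, with distinct sequences (log2 0.98) and with 21- to 23-nt reads that start with G (log2 0.82). Histone genes numbered 2 higher, 1 lower and 4 neither (median 0.49, percentile 86.61), with his-24 at log2 0.26 and his-35 at log2 0.49. ERGO-1 targets had 5 of 9 lower and 2 higher, with a median of −1.39 at percentile 0.07. F39F10.4 was 69.01 times lower (47.6 to 104.1) and E01G4.5 19.7 times lower (17.3 to 22.6).

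The largest ratios upwards were nlp-40, a neuropeptide gene (177-fold, 60.1 to 861, from 3 DA1316 reads), the hedgehog-related wrt-5 (143.3-fold, 48.6 to 698, from 3 reads), ndx-2 (107-fold, 49.03 to 294), Y47G6A.5 (98.3-fold, 47.4 to 246) and zip-7 (96.1-fold, 43.8 to 263). No DA1316 read was counted for ddn-1, which was at least 63.8-fold higher against a floor of 3 reads. Downwards, C44C1.1 on X had no read in csr-1 and was at least 91.4 times lower. Next came gsto-3 (188 times, 51.6 to 1553, 2 reads in csr-1), Y57G7A.2 (245 times, 43.7 to 9721, 1 read), jmjd-3.2, a histone demethylase gene (103.6 times, 44.2 to 320), inso-1 (92.5 times, 44.7 to 231) and F39F10.4. Reads of nlp-40 spanned chromosome I 11620 to 16833, those of gsto-3 chromosome III 378196 to 381297 and those of C44C1.1 chromosome X 980773 to 983022.

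X-linked genes stood apart in csr-1, where 265 of 309 measured (85.8%) were lower, with a median log2 ratio of −2.89 (−3.04 to −2.69), against 27.8% of autosomal genes with a median of −0.18. Within the genes that were higher in the IP, 45 X-linked genes had a median of −2.42, which differed by −2.23 from autosomal lists of equal level and lay below all 10000 of them. Of 157 X-linked genes higher in the IP, only these 45 were measured in csr-1 against DA1316, compared with 3739 of 4777 over all chromosomes. In ego-1, 81.3% of X-linked and 73.5% of autosomal genes were lower, with medians of −3.02 and −2.38. X-linked genes differed from autosomal lists of equal level by −0.64, below all 10000 of them. Within the genes called neither way in the IP that difference was −2.07 in ego-1 and −2.28 in csr-1, and within the genes higher in the IP it was −0.11 in ego-1 (percentile 23.99). In N2 input against DA1316, 45.02% of X-linked and 31.7% of autosomal genes were lower, with medians of −0.86 and −0.79. Within the genes higher in the IP the difference from matched lists was −0.35 in that comparison, below all 10000 of them. In the IP 44.7% of measured X-linked genes were higher, against 76.8% to 82.4% on the autosomes, without matching on level. The matched comparisons were chosen after the chromosome counts were seen.

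**Figure D2:**
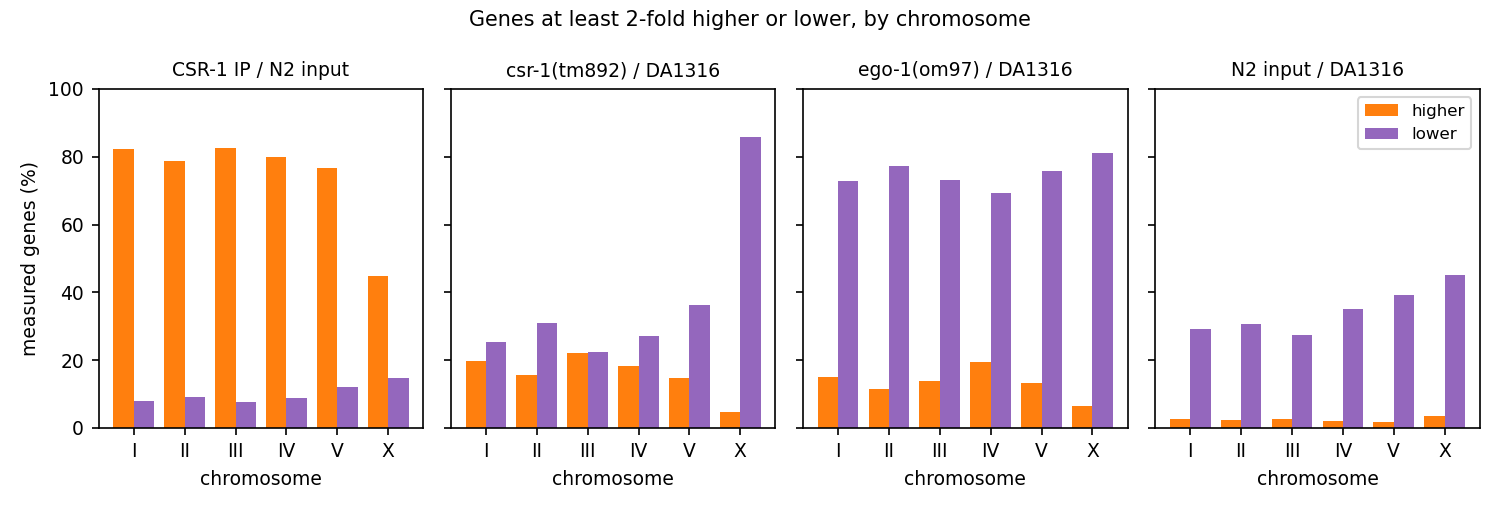
Percentage of measured protein-coding genes (y axis) called higher (orange) or lower (purple) on each chromosome (x axis), 1 panel per comparison. On X, 85.8% of genes are lower in csr-1 and 44.7% are higher in the CSR-1 IP, against 22.4 to 36.2% and 76.8 to 82.4% on the autosomes.

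The ego-1(om97) library was compared with DA1316 in the same way, to ask which small RNAs depend on the polymerase EGO-1. Antisense small RNAs were lower for nearly all germline lists. Those of the ego-1 gene were 29.9 times lower (12.5 to 75.4) and those of csr-1 14.6 times lower (8.59 to 26.997), which again do not check the genotype. With whole genes in place of exons the log2 ratio of csr-1 turned to 1.39 and the gene was not measured. Of 5860 genes measured, 4333 were lower and 831 higher, with a median log2 ratio of −2.41, and of 328 pseudogenes 170 were lower and 62 higher. With miRNA reads as the normaliser 3091 were lower and 1257 higher, with the median shifted by 0.76, and 28.9% of calls were higher in place of 16.1%. All genome-matched reads shifted the median by −0.30. Centred on the median gene, 1366 were lower and 1842 higher, and the medians of the Argonaute (0.016), histone (0.55), neuronal (0.035) and ERGO-1 target lists (1.32) turned positive.

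All 44 measured chromosome segregation genes and all 31 oocyte and maternal genes were lower, with median log2 ratios of −3.54 and −3.58. Neither median was reached by any of 10000 lists of equal level. With members at 0 reads set to their bound the oocyte median was −3.41. The centromeric histone gene hcp-3 had no read in ego-1 and was at least 43.5 times lower, klp-7 was 20.9 times lower (13.1 to 35.5), cls-2 15.5 times (10.7 to 23.5), rme-2 28.9 times (11.12 to 107) and glp-1 6.49 times (4.05 to 10.97). Meiosis genes were lower in 34 of 37 cases (median −3.49, percentile 0; −3.34 with members at 0 reads at their bound), with htp-1 62.2 times (21.1 to 304) and hal-2 12.98 times lower (6.70 to 28.8). Cell cycle genes were lower in 35 of 36 cases (median −3.44, percentile 0.01; −3.33 at the bound), with top-2 28.9 times (15.0 to 69.6) and plk-1 10.8 times lower (6.61 to 18.7). Chromatin genes were lower in 31 of 33 cases (median −3.25, percentile 0.07), with isw-1 14.4 times (8.14 to 28.2) and set-2 11.59 times lower (6.53 to 20.7). P granule genes were lower in 14 of 15 cases (median −3.44, percentile 0.29; −3.36 at the bound), with pgl-1 41.6 times (17.7 to 128.9) and glh-4 34.1 times lower (14.2 to 85.8). The other 1 was glh-1, at log2 −0.99. Beside these lists, 21U-RNAs in RPM were 2.62-fold higher in ego-1 than in DA1316, and 1.53-fold higher when only reads of 21 nt were counted (35.4% of 21U-RNA reads in ego-1, 60.5% in DA1316). N2 input was itself 1.92-fold above DA1316, and 3.09-fold with reads of 21 nt. Reads of 17 to 20 nt made up 33.99% of antisense reads, against 15.8%, and the mir-35 family was 31.9 times lower (30.4 to 33.6) while other miRNAs were 1.66 times lower.

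The biogenesis list had 18 of 22 lower and 1 higher (median −3.16, percentile 0.18). The higher gene was rde-11, at 4.17-fold (3.82 to 4.56). Argonaute genes were lower in 12 of 14 cases (median −2.39, percentile 21.33), with hrde-1 4.67 times (3.65 to 6.05) and prg-1 3.38 times lower (2.79 to 4.11), and alg-3 and alg-4 higher. The prg-1 call ended with miRNA scaling. Ribosomal protein genes were lower in 22 of 23 cases, with a median of −2.79 at percentile 85.5, or −2.44 at the bound. Among them rpl-13A, with no read in ego-1, was at least 16.1 times lower and rpl-11.1 17.7 times (4.69 to 149), and rpl-42 was higher. Of 5 histone genes 4 were lower (median −1.86, percentile 55.29), with his-35 4.51 times lower (2.84 to 7.62) and his-24 (log2 0.84) not called.

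Of 11 measured sperm genes in ego-1, 6 were higher, all on few reads, 4 were lower and 1 was neither, and the list median was above 0 at percentile 99.91. The higher ones reached the minimum level only in ego-1, and the lower ones except spe-41 only in DA1316. Which genes were measured thus depended on the change itself, and so did the median and percentile. A pair of the higher ones had identical counts, from reads that all match more than 1 place. With this pair taken once, 5 of 10 were higher and the percentile was 99.82, in a separate random draw that gave 99.95 with each gene counted. With 21- to 23-nt reads that start with G all 6 higher ones fell below the minimum level, so the list median under that choice (−2.76) rests on the 4 lower genes alone. The lower ones included spe-41 (3.56 times, 2.38 to 5.51, without a call under miRNA scaling) and spe-39 (6.72 times, 2.72 to 21.5). Of 8 neuronal genes 5 were lower and 3 higher (median −2.37, percentile 49.33; −2.25 at the bound), with unc-10 46.96 times (26.1 to 94.3) and unc-17 29.1 times lower (9.76 to 142.5). From the muscle list pat-3 was 6.96 times lower (3.41 to 16.6) and ttn-1 (log2 0.08) was not called. No intestinal gene was measured. The cuticle gene noah-2 was 44.03 times lower (7.64 to 1755, 1 read in ego-1) and the collagen gene bli-6 14.7-fold higher (3.78 to 140), which fell below the minimum level with 21- to 23-nt reads that start with G and with all genome-matched reads as the normaliser. ERGO-1 targets numbered 5 lower, 3 higher and 1 neither (median −1.09, percentile 23.57), with F39F10.4 233 times (107 to 636) and E01G4.5 28.4 times lower (23.7 to 34.7).

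The largest ratios upwards in ego-1 were nlp-40 (208-fold, 70.5 to 1012), ndx-1 (167-fold, 45.5 to 1387, from 2 DA1316 reads), T23F6.3 (93.8-fold, 50.6 to 197), the coronin gene cor-1 (86.1-fold, 49.9 to 162), R11E3.2 (59.4-fold, 33.6 to 116) and dos-2, without a DA1316 read and at least 63.2-fold higher. Downwards, besides F39F10.4 and hcp-3, they were dyf-17 (280 times, 50.1 to 11095, 1 read in ego-1), F02E11.4 (110 times, 50.5 to 301), F20D6.10 (at least 44.2 times) and T24A6.20 (at least 43.3 times). Reads of F39F10.4 spanned chromosome X 16902309 to 16903628 and those of hcp-3 chromosome III 9615204 to 9616371.

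**Figure D3:**
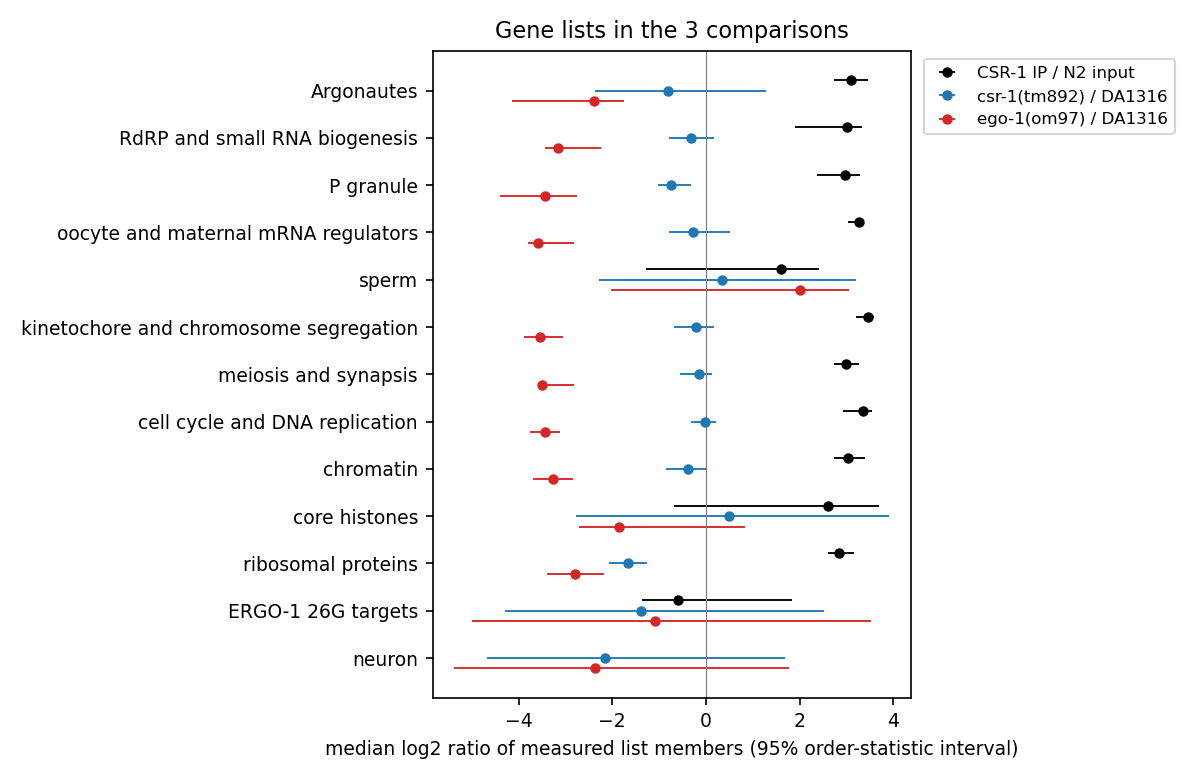
Median log2 ratio (x axis) of the measured members of each fixed gene list, with its 95% order-statistic interval, for CSR-1 IP over N2 input (black), csr-1 over DA1316 (blue) and ego-1 over DA1316 (red). For the 48 measured chromosome segregation genes the median is 3.46 in the IP, and for those measured in the mutants it is −0.22 in csr-1, which turns to 0.80 with miRNA reads as the normaliser, and −3.54 in ego-1.

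The IP sets were then followed into the mutants, which share no library with the IP and its input. Genes higher in the IP had a median log2 ratio of −0.22 in csr-1 (−0.27 to −0.17, 3739 genes), which turned to 0.76 with miRNA reads as the normaliser. Of them 889 (23.8%) were lower in csr-1, against 1064 for independent lists, and 396 were higher, against 567. In the same 3739 genes the count of 889 became 192 with miRNA scaling and 642 when centred on the median gene. The count of 396 higher became 1547 and 631, so with miRNA scaling more of these genes were higher than lower. In ego-1 the same set had a median of −2.81 (−2.83 to −2.76, 3546 genes), a 7.00-fold lower level, and −2.08 with miRNA scaling. Of these 3289 (92.8%) were lower in ego-1, against 2906 for independent lists, and in the same genes the count became 2420 with miRNA scaling and 981 when centred on the median gene. Genes lower in the IP had medians of 0.72 in csr-1 (0.44 to 0.94) and −0.11 in ego-1 (−0.28 to 0.04), and the latter turned to 0.74 with miRNA scaling. Of the genes lower in the IP, 242 were higher in csr-1 and 167 in ego-1, against 84.2 and 32.3 for independent lists. Genes called neither way in the IP had medians of −1.39 in csr-1 and −1.89 in ego-1. These became −0.41 and −1.08 with miRNA scaling, and −1.12 and 0.52 when centred on the median gene. In reads, the genes higher in the IP took 89.4% of antisense reads in the IP, 35.2% in N2 input, 33.2% in csr-1, 12.3% in ego-1 and 42.02% in DA1316. Genes lower in the IP took 3.596%, 37.9%, 43.4%, 49.7% and 28.9%. Across genes, which are not independent replicates, the IP ratio correlated with the csr-1 ratio at Pearson's r 0.0592 and Spearman's rho 0.18 (5035 genes). With the ego-1 ratio the values were r −0.484 and rho −0.39 (4838 genes).

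**Figure D4:**
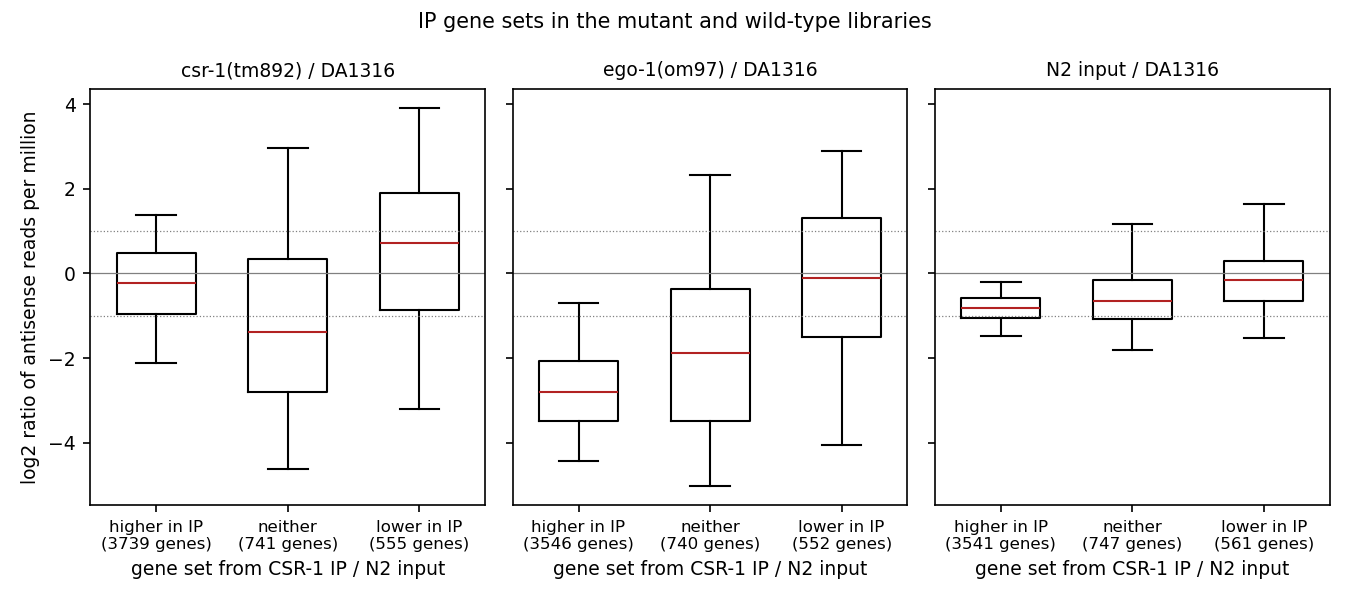
Log2 ratio of antisense RPM (y axis) of genes higher in, lower in or neither way in the CSR-1 IP (x axis), in csr-1, ego-1 and N2 input, each over DA1316. Boxes show the quartiles, red lines the medians, whiskers the 5th and 95th percentiles and dotted lines the 2-fold limits, and the genes higher in the IP have medians of −0.22, −2.81 and −0.81. N2 input also entered the choice of the IP sets, so the last value is not independent of them.

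Both mutants were compared with the same DA1316 library, so their ratios share its chance values. In both, 1694 genes were lower, of 5436 measured in both. Independent lists would share 1416. The count of 1694 became 654 with miRNA scaling and 568 when centred on the median gene. Unchanged libraries simulated against the same control shared 1.18 genes with counting error alone and 209.6 with the spread between N2 input and DA1316 added. That added spread held no general shift, whereas N2 input had a median log2 ratio of −0.79 over DA1316. How many genes a general shift of DA1316 would put lower in both was not simulated. With the reads of DA1316 split in 2 parts, 1 for each mutant, 1545 genes were lower in both. The covariance of the log2 ratios was 1.82, against 0.0363 and 0.332 in the simulations, and the correlation across genes was 0.574, against 0.433 and 0.518. The shared control is 1 library, so its own differences from other wild-type animals enter both ratios. Genes higher in both numbered 372, against 67.1 for independent lists. The simulated libraries shared 1.29 such genes with counting error alone and 184.9 with the added spread, and the split control also gave 372. Among the 4817 genes measured in all 3 comparisons, 3532 were higher in the IP. Of these 869 were lower in both mutants, 2156 were lower in ego-1 and neither way in csr-1, 264 were lower in ego-1 and higher in csr-1, and 171 were neither way in both. Set directly against each other, 3129 of 4625 genes were higher in csr-1 than in ego-1 and 544 lower, with a median log2 ratio of 1.95.

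N2 input and DA1316 carry neither mutation and served as a yardstick, although strain, selection and preparation differ and they are not replicates. Of 5328 genes, 123 were higher and 1732 lower in N2 input, with a median log2 ratio of −0.79. All genome-matched reads as the normaliser gave 170 higher and 794 lower, a share of 17.6% higher in place of 6.63%, with the median shifted by 0.27. Counting distinct sequences gave 536 and 1060, and centring gave 325 and 313. With miRNA scaling 76 were higher and 1968 lower, and the median moved by −0.14. The chromosome segregation list had a median of −0.98 in this comparison, so that its csr-1 median of −0.22 lay nearer 0 than that of the yardstick and its ego-1 median of −3.54 farther. The other lists measured in at least 3 genes had medians between −1.62 (neurons) and −0.03 (ERGO-1 targets). The ribosomal protein, histone, neuronal and ERGO-1 target medians lay farther from 0 in csr-1 than in N2 input. The medians of the remaining lists lay nearer 0 in csr-1. Of 3541 genes higher in the IP, 1039 (29.3%) were lower in N2 input, against 889 of 3739 (23.8%) in csr-1. N2 input is also the denominator of the IP ratio, so a low N2 input count favours both calls. In N2 input over DA1316 the medians were −0.81 for genes higher in the IP, −0.65 for neither and −0.16 for lower. For the IP sets this comparison is therefore no independent yardstick.

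The position of reads along genes also differed. In the genes higher in the IP with at least 20 reads in both libraries, 71.9% of antisense reads in csr-1 lay in the last of 3 equal parts of the gene, towards the 3′ end, against 45.1% in DA1316 (means over 2890 genes). The share was higher in csr-1 for 2721 of these genes (94.2%), with a mean difference of 26.8 percentage points. N2 input exceeded DA1316 by 7.43 points (3202 genes), the IP exceeded its input by 3.13 points (3228 genes) and ego-1 exceeded DA1316 by 2.595 points (296 genes). In the genes lower in the IP, csr-1 and DA1316 differed by −0.18 points (465 genes), and N2 input exceeded DA1316 by 1.61 points (535 genes). This measure was chosen after the ratios were seen.

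**Figure D5:**
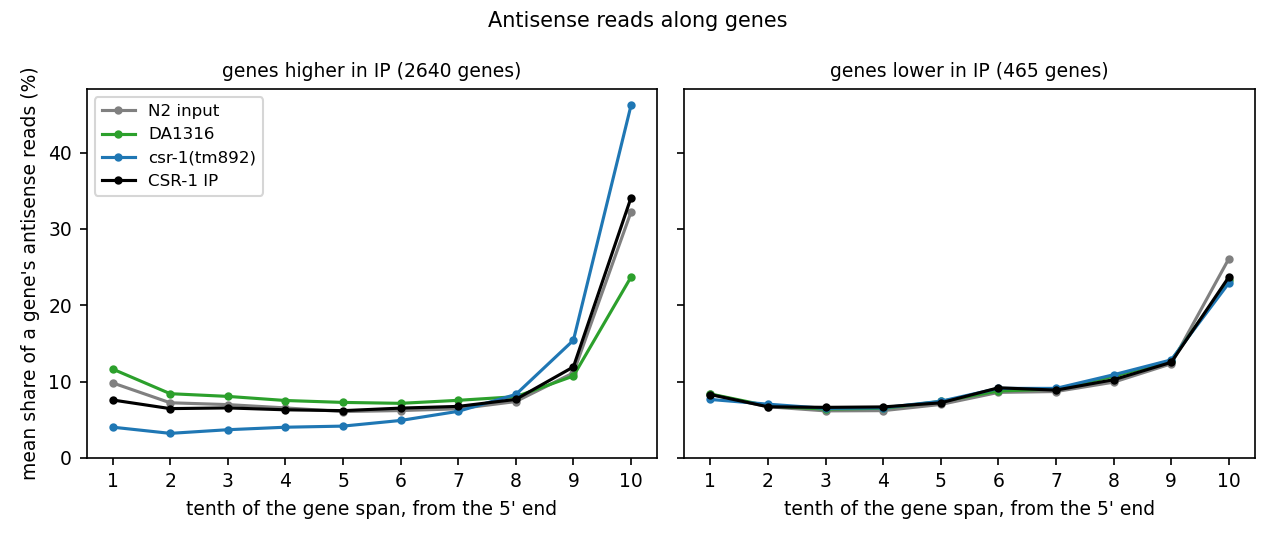
Mean share of a gene's antisense reads (y axis, %) in each of 10 equal parts of the gene span from the 5′ end (x axis), for genes higher in the IP (left) and lower in the IP (right, with 464 genes in the CSR-1 IP and 465 in the other libraries), 1 line per library. In the last part the genes higher in the IP hold 46.2% of their reads in csr-1, 34.1% in the CSR-1 IP, 32.2% in N2 input and 23.7% in DA1316.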

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

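Genes with opposite calls in the csr-1 and ego-1 libraries, both against DA1316, were singled out because the mutants differed in direction there. Of 5436 genes measured in both, 288 were higher in csr-1 and lower in ego-1, against 667 for independent lists. Only 5 were lower in csr-1 and higher in ego-1, against 142.4 for independent lists: srt-17, Y17D7C.6, H40L08.3, F38E11.9 and Y20F4.4, named after their values were seen. Both counts lay below those of independent lists. The shared DA1316 library by itself makes opposite calls rarer, and no value for unchanged libraries was computed for these counts. The difference between the mutants was not tested, since each is 1 library.

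Reads from mitochondrial DNA, which no comparison used, made up 1.88% of the CSR-1 IP (1.85 to 1.90%, exact Clopper-Pearson interval). They made up 0.286% of N2 input, 0.268% of csr-1, 0.380% of ego-1 and 0.388% of DA1316. Outside mitochondrial rRNA and tRNA the share was 0.121% in the IP and 0.195% in its input, so the excess lay in fragments of those RNAs. No biological explanation was tested.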

How the results depend on the processing

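Of the counts and shares, 97 values under an alternative stayed within the limit (1.5 times the count, or the share's interval) and 62 moved beyond it. Of the list medians 218 stayed, 69 moved and 10 reversed, where reversed means that a median past 2-fold, or a called gene, changed sign. A further 18 list medians changed sign from within 2-fold, 8 of them in csr-1 with miRNA reads as the normaliser. The genes measured can differ between settings. With the members of the main analysis held, 6 of the 10 and 15 of the 18 still changed sign. Of the values of named genes 1185 stayed, 296 moved and 19 reversed. Counts stayed within 1.5 times with a pseudocount of 0.1 RPM, reads with 1 match, whole genes and reads of at least 21 nt. Except where the construction is named, the cause was not tested. Reads of at least 21 nt, centring on the median, the IP set held, list members held, 21U-RNA reads of 21 nt only and sperm genes with identical counts taken once were chosen after seeing the data.

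With miRNA reads as the normaliser, the values beyond the limit were 26 genes lower in the IP, 2673 higher and 718 lower in csr-1, 1257 higher in ego-1, 654 lower in both mutants and 420 higher in the IP and lower in csr-1 (of 4260, since the IP calls change too; 192 with the IP set held). The csr-1 medians of ribosomal protein (0.60) and neuronal genes (0.38) are counted as reversed because other members were measured, and the same genes stayed below 0 (−0.77 and −1.29). The medians of the Argonaute, biogenesis, P granule, oocyte, segregation, meiosis, cell cycle and chromatin lists, within 2-fold before, turned positive with the same members too. The IP log2 ratios of spe-41 (0.12) and his-24 (0.087) reversed too. With all genome-matched reads 641 were higher in csr-1, 443 were higher in ego-1 and 964 differed between N2 input and DA1316.

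A minimum of 25 RPM gave 877 lower in csr-1, 2098 lower and 429 higher in ego-1, 844 lower in both, 408 and 1505 higher in the IP and lower in csr-1 or ego-1, and 938 between N2 input and DA1316, since fewer genes can pass. No minimum beyond 1 read gave 1463 lower in the IP, 1571 higher and 3722 lower in csr-1, 1988 higher and 6952 lower in ego-1, 3092 lower in both, 1429 higher in the IP and lower in csr-1, and 3922 between N2 input and DA1316, since more genes can pass. A fold of 4 gave 108 lower in the IP, 413 higher and 841 lower in csr-1, 548 higher in ego-1, 725 lower in both, 97 higher in the IP and lower in csr-1, and 245 between N2 input and DA1316.

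With 21- to 23-nt reads that start with G, 363 genes were higher in ego-1 and the sperm list median in ego-1 is counted as reversed (−2.76) because only its 4 lower genes were still measured. Counting distinct sequences gave 1974 lower in the IP, 2878 lower in csr-1, 1372 higher in ego-1 and 2629 lower in both. It also gave 6 lists past 2-fold in csr-1 and a sperm median in the IP (−2.08) that is counted as reversed because 11 genes were measured in place of 3, which themselves had a median of 0.81.

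Centring on the median gave 784 higher and 1726 lower in the IP, 1366 lower and 1842 higher in ego-1, 568 lower in both, 31 (of 634) and 215 (of 586) higher in the IP and lower in csr-1 or ego-1, and 638 between N2 input and DA1316. The lists past 2-fold numbered 2 in the IP and 7 in ego-1. In the IP the sperm (−1.07) and histone medians (−0.077) reversed, as did the log2 ratios of prg-1 (−1.23), glp-1 (−0.51), spe-39 (−0.27), cls-2 (−0.83), hal-2 (−0.23), cdk-1 (−0.061), lin-35 (−0.36), rpl-13A (−1.01), pat-3 (−0.22), vit-6 (−0.28), snb-1 (−0.090) and E01G4.5 (−0.24). In ego-1 the Argonaute (0.016), histone (0.55), neuronal (0.035) and ERGO-1 target medians (1.32) reversed, as did prg-1 (0.66), hrde-1 (0.21), spe-41 (0.63) and his-35 (0.32). Centring takes the general shift out by construction, and the smaller IP set enters the counts of 31 and 215. With the IP set held, 642 and 981 were lower in csr-1 and ego-1.

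With whole genes the csr-1 gene reversed in ego-1 (log2 1.39) and was not measured in the IP, unc-17 was not measured in either mutant, and noah-2 lost its call in both, because a read that also lies in an overlapping gene is not counted under that choice.

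The antisense share with reads of 1 match, with distinct sequences and without structural RNA was 64.45%, 78.61% and 65.15% in the IP, 18.94%, 54.48% and 18.82% in N2 input, 27.57%, 53.64% and 36.14% in csr-1, 12.27%, 31.85% and 18.26% in ego-1, and 25.82%, 55.08% and 28.67% in DA1316. The last change follows from the smaller denominator.

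No paired analysis was possible because each group has 1 library, and for the same reason no library can be left out. The CSR-1 IP had the fewest non-structural reads (1232572), followed by ego-1 (1536409). In ego-1, 415 measured genes had 0 reads, for which only bounds hold. Muscle, intestine and cuticle lists had too few measured genes for a median.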

Other observations

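The tests of oocytes or embryos in csr-1 and all 3 tests in ego-1 were chosen only after the results were seen, as were the miRNA families described here. The mir-51 family (6 members) was retained in the CSR-1 IP at 84.7% of its input level, with members between 56.1% and 126%, while other miRNAs stood at 29.4%. At the other end, mir-73 and mir-74 had 1 read each in the IP against 7274 and 4578 in the input. Of the 372 genes higher in both mutants, 229 were measured in the IP, where 150 were lower, 17 higher and 62 neither, and 5 of the 372 lay on X. Over all genes measured in the IP 9.2% were lower and 78.3% higher, and 309 of 5739 genes measured in csr-1 lay on X. The mutants share the DA1316 library, and simulated unchanged libraries with the added spread already shared 184.9 genes higher in both.

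Antisense reads of genes higher in the IP lay nearer the 3′ end in csr-1 than in DA1316. Short or degraded reads are argued against as the whole cause, since with 21- to 23-nt reads that start with G the mean difference was 27.13 points. Reads shared between paralogs are argued against by a difference of 26.8 points with reads that match 1 place. A shift of equal size in all genes of the library is argued against by genes lower in the IP, whose difference was −0.1762 points. N2 input exceeded DA1316 by 7.433 points in genes higher in the IP and by only 1.607 points in genes lower in the IP. A difference between libraries that acts mainly on genes higher in the IP therefore cannot be excluded by this test. An effect of the csr-1 mutation stays open and was not tested apart from preparation, since each group has 1 library.

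X-linked genes were lower in csr-1 than autosomal genes. Differences in level or IP class are argued against as the whole cause for the 45 X-linked genes that were higher in the IP and measured in csr-1. They lay −2.225 (log2) from autosomal lists of equal level. Fewer oocytes or embryos in the csr-1 animals cannot be told apart from an effect of the mutation: the oocyte and maternal list had a median of −0.2757, while the mir-35 family was 8.31 times lower. A difference in the stage or cells of the animals may therefore underlie part of the pattern.

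Genes higher in the IP were lower in ego-1. Short or degraded reads are argued against as the whole cause, since genes lower in the IP, from the same library, had a median log2 ratio of −0.1076. Fewer germ cells are argued against as the whole cause by 21U-RNAs, which were 2.616-fold higher in ego-1 than in DA1316, and 1.53-fold higher with reads of 21 nt only. These values are shares of non-structural reads, in which miRNAs stood at 0.550 and exon antisense reads at 0.634 of their DA1316 level. The amount of 21U-RNAs per animal was not measured. A smaller loss of germ cells stays open, since N2 input was 1.919-fold above DA1316 (3.087-fold at 21 nt), a wide spread between libraries without either mutation. Fewer oocytes or embryos cannot be told apart from an effect of the mutation, since the mir-35 family stood at 0.03131 of its DA1316 level. No test here bears on how the mutation would act.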
